A study of Homo sapiens with 8 samples.

How the data were processed

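Gene expression was measured on 8 Affymetrix arrays of 54675 probe sets in DND-41 and KOPT-K1, 2 established human T-cell acute lymphoblastic leukaemia lines. Per the labels, each line was sampled as naive cells treated with vehicle and as persister cells kept in 1 uM of the gamma-secretase inhibitor Compound E for at least 7 weeks. Each of the 4 groups held 2 replicates. Total RNA was taken with Trizol and turned into biotin-labelled cRNA, per the labels' protocols. The labels do not say whether replicates of a group came from separate cultures, so the p-values describe the spread between these samples. They give no batch, date or scan order either.

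The deposited values are probe set intensities from GCRMA 2.30.0, per the submitters' processing notes, which state no other step. GCRMA corrects for background, normalizes over arrays and summarises the probes of a set. The values lay on a linear scale in every array, from 4.71 to at most 87651, and log2 was taken before any test, as the design provided for a linear column. All analyses below started from these values.

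The table paired 41097 probe sets with 1 gene symbol, 1801 with several and 11721 with none, and 62 were array controls, 6 of which carry a symbol and are counted there too. Symbols were checked against the NCBI gene table by Entrez identifier. Of these identifiers 54 had no match, and no symbol needed an update. GCRMA places unexpressed probe sets at a common low value, here log2 2.24, and 62.4% of all values lay at or under log2 4. A probe set entered the tests if its log2 value was above 4 on at least 2 of the 8 arrays. This left 18899 probe sets with 1 symbol, and 12197 probe sets were constant over all arrays. Each gene was represented by its probe set of highest mean over the 8 arrays, which gave 10174 genes, of which 5060 had several measured probe sets. Where both arrays of a group lay at or under log2 4, a fold is given as a lower bound, from the mean of the brighter group against log2 4.

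Differences were tested with limma 3.58.1 in R 4.3.3. The fit held 4 group means over all 8 arrays, with 4 residual and 2.69 prior degrees of freedom. Its contrasts were persister minus naive in each line, the difference of these changes (KOPT-K1 minus DND-41), their mean, and KOPT-K1 naive minus DND-41 naive. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and an adjusted p under 0.05 is called past the threshold. Fisher's exact test (two-sided) compared the genes past the threshold in both lines. On data simulated from these arrays for the DND-41 comparison, over 10174 genes, the fit found 68 of 100 genes changed by log2 1 and 98 of 100 changed by log2 2, with 13 false calls. For the KOPT-K1 comparison over the same 10174 genes it found 69 of 100 and 97 of 100, with 14 false calls. The simulation gave each gene the same spread in all 4 groups. The real SD between replicates was 0.414 in DND-41 persister cells and 0.164 in DND-41 naive cells. It therefore does not show how the fit performs under the unequal spread of the DND-41 comparison. The number of arrays limits the precision.

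Before the data were examined, 32 gene lists were fixed, and 28 had enough measured members to be tested. Lists were compared with all other genes by limma's camera at a preset correlation of 0.01, two-sided, with adjustment over the lists. Camera with an estimated correlation and fry, which asks only whether a list's genes move one way on balance, were alternatives. A list's value is the median log2 change of its measured members minus the median of all genes. The genes named in the text were also set by a rule fixed before the data were examined. The rule took 11 Notch pathway and related genes whatever their result, and in each line the 6 highest and 6 lowest changes among genes past the threshold with a group mean of at least log2 6 and arrays that did not overlap. It added up to 3 members of each list that passed its test or had at least 5 members past the threshold, up to 2 markers of each other cell type, and the 5 highest and 5 lowest genes for the difference between lines and for the naive lines. Not all genes under the rule are printed. Of these fixed genes, 1 is not reported here.

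Alternatives set before the data were examined were no filter, a filter at log2 6, every probe set on its own, the mean of a gene's probe sets, quantile normalization, median centring, an intensity trend with a robust prior, each line fitted alone, the replicate number as a block, a 2-fold minimum, an adjusted p under 0.01, and leaving out each of the 8 arrays. Added after the data were seen were the 3'/5' signal ratio of ACTB and GAPDH as a covariate, the median of 18 bacterial hybridization control probe sets as a covariate, and crossed replicate numbers in DND-41. The choice of probe set per gene was held at that of all 8 arrays in the leave-one-out and quantile settings, which was decided after HES1 changed sign with the probe set used. Replicates of the same number did not deviate together, with correlations of -0.445 in DND-41 and -0.0523 in KOPT-K1, so the numbers were not used as pairs.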

Results

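T-cell acute lymphoblastic leukaemia often depends on Notch signalling, and gamma-secretase releases the active part of Notch receptors from the membrane. Persister cells are those that went on growing after weeks of gamma-secretase inhibition. RNA from naive and persister cells of the lines DND-41 and KOPT-K1 was measured on 8 arrays, 2 for each of the 4 groups, and 10174 genes were tested. Between 36.3% and 38.3% of probe sets per array lay above log2 4. The SD between replicates over all genes was 0.164 in DND-41 naive, 0.414 in DND-41 persister, 0.15 in KOPT-K1 naive and 0.219 in KOPT-K1 persister cells. Gene changes below are log2 differences of group means ± the standard error from limma, with 2 arrays per group and Benjamini-Hochberg adjusted p-values.

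Array controls moved with 2 of the groups. The 3' signal of ACTB and GAPDH exceeded their 5' signal by a mean log2 of 3.17 on DND-41 persister array 1, against 1.71 on persister array 2 and 0.993 to 1.64 on the other 6. The bacterial hybridization controls, added before hybridization in the standard protocol of these arrays, had a median log2 value of 13.35 and 12.94 on the KOPT-K1 persister arrays. On the other arrays they lay between 10.93 and 11.96, so that they were 3.21-fold higher in KOPT-K1 persister than in naive cells.

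**Figure D1:**
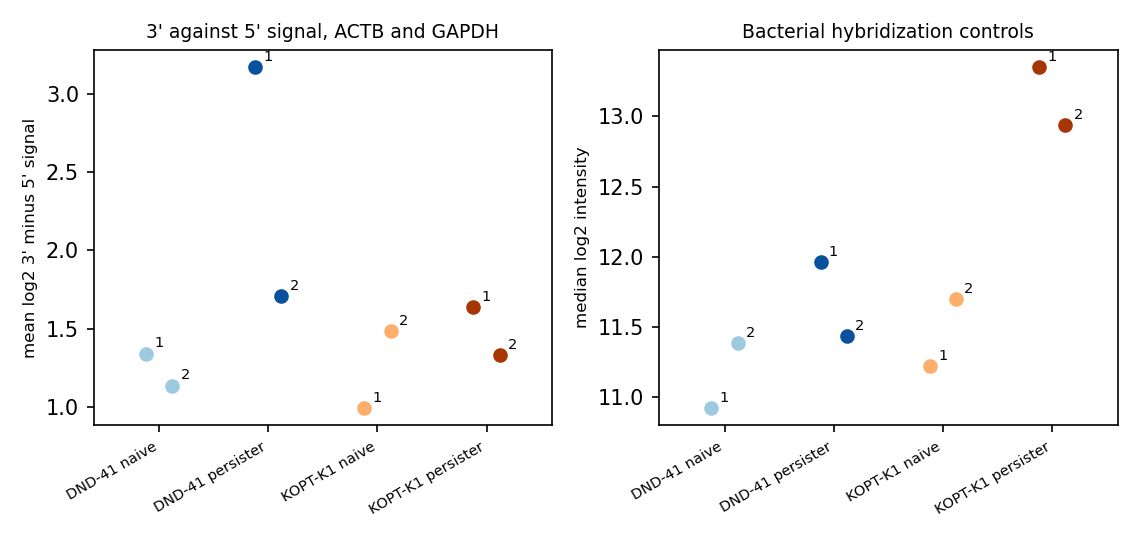
The left panel plots, for each of the 8 arrays, the mean log2 difference between 3' and 5' probe sets of ACTB and GAPDH, and the right panel the median log2 intensity of 18 hybridization control probe sets; digits are replicate numbers. DND-41 persister array 1 stands at 3.17 on the left, and both KOPT-K1 persister arrays stand above the other arrays on the right, at 13.35 and 12.94.

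Genes of the Notch pathway were examined to see how signalling stood in cells that grow with gamma-secretase inhibited. DTX1, a ubiquitin ligase gene switched on by Notch, was high in both naive lines and at background in both persister lines. It fell from log2 9.78 to below 4 in DND-41, at least 55-fold (adjusted p = 1.8e-05), and from 9.03 to below 4 in KOPT-K1, at least 32.7-fold (adjusted p = 1.15e-05). The receptor gene NOTCH1 went opposite ways. It fell from 10.46 to 8.60 in DND-41 (-1.86 ± 0.12, adjusted p = 0.000301) and rose from 10.44 to 10.97 in KOPT-K1 (0.53 ± 0.12, adjusted p = 0.00916), and the 2 changes differed by 2.39 (adjusted p = 0.000203). The rise in KOPT-K1 was not past the threshold without naive array 1 (adjusted p = 0.0561), without naive array 2 (0.0594), or with the hybridization controls as a covariate (0.48, adjusted p = 0.299). NOTCH3 fell at least 3.05-fold in DND-41 (adjusted p = 0.000375) and lay under log2 4 in both KOPT-K1 groups.

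HES1, the classical Notch target and a transcriptional repressor, rose in KOPT-K1 from 7.28 to 10.36 (3.08 ± 0.11, adjusted p = 1.15e-05), to the level of naive DND-41 cells at 10.41. In DND-41 it fell by 1.01 ± 0.11 (adjusted p = 0.00291), but its other probe set changed by 0.30 there, so the direction in DND-41 depends on the probe set, and the mean of both gave -0.36 (adjusted p = 0.0841). In KOPT-K1 the other probe set changed by 2.63. HES4 lay at background in DND-41 and was at least 1.65-fold lower in KOPT-K1 persister cells (adjusted p = 3.47e-05). PTCRA, the pre-T-cell receptor alpha chain, stayed near background in all groups, with changes of 0.25 (adjusted p = 0.275) and 0.00, and NRARP was under the filter, with no value above log2 2.66.

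The growth regulator MYC fell in both lines, by 0.75 ± 0.15 in DND-41 (adjusted p = 0.0218) and by 1.40 ± 0.15 in KOPT-K1 (adjusted p = 0.000534), a difference of -0.65 (adjusted p = 0.0509). In DND-41 the call was lost without naive array 1 (adjusted p = 0.136), naive array 2 (0.125), either KOPT-K1 naive array (0.0524 each), or with either covariate (-0.54, 0.0886 for the 3'/5' ratio and -0.66, 0.106 for the hybridization controls). With the hybridization controls as a covariate the KOPT-K1 change was -1.11 (adjusted p = 0.101). IL7R, the interleukin-7 receptor, fell at least 4.12-fold in KOPT-K1 (adjusted p = 3.57e-05; other probe set -1.76), where its level was low. In DND-41 its brighter probe set changed by -0.25 (adjusted p = 0.417; -0.53 and 0.0081 without persister array 2) and its other by -3.27. The survival gene BCL2 rose in DND-41 from 11.40 to 12.21 (0.81 ± 0.13, adjusted p = 0.0127), not past the threshold without naive array 1 (0.109) or naive array 2 (0.0878). It changed by -0.38 in KOPT-K1 (adjusted p = 0.0528), with a difference between lines of -1.19 (adjusted p = 0.00499), while its other probe set changed by 0.36 in DND-41 and -1.47 in KOPT-K1.

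**Figure D2:**
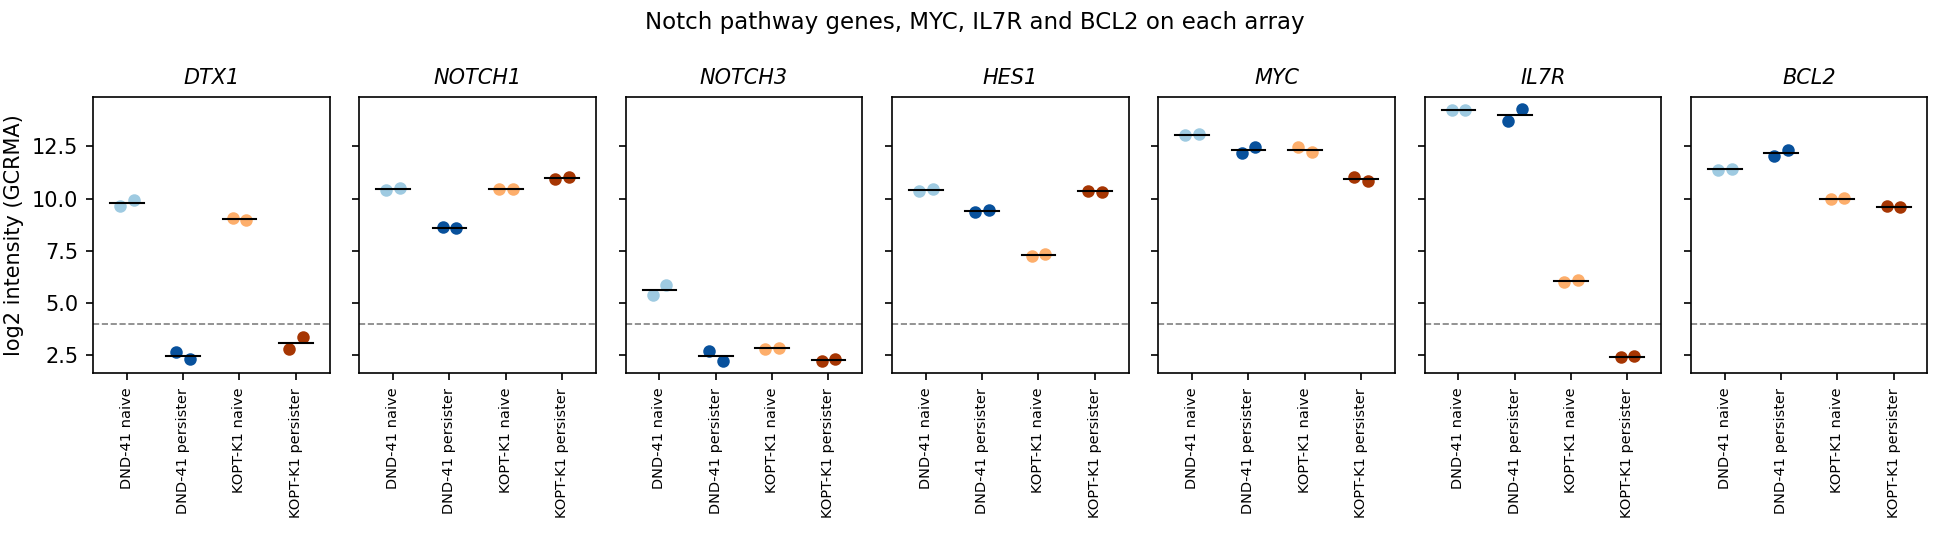
Each panel plots the log2 intensity of the gene named above it on every array (points) and the mean of each group of 2 arrays (bars); the dashed line marks log2 4. DTX1 drops below the line in both persister groups, while NOTCH1 and HES1 sit lower in DND-41 and higher in KOPT-K1 persister cells.

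The strongest rises in DND-41 persister cells were in JCHAIN, GZMA and NOG. JCHAIN, the immunoglobulin joining chain, rose from log2 7.85 to 14.20 (6.34 ± 0.23, adjusted p = 3.3e-05), and GZMA, a cytotoxic protease, rose at least 29-fold from background (adjusted p = 5.52e-05). NOG, an antagonist of bone morphogenetic proteins, rose by 5.38 ± 0.23 (adjusted p = 6.62e-05). TSC22D3, the glucocorticoid-induced leucine zipper, rose at least 15.6-fold, the scaffold gene IQGAP2 at least 16.2-fold and the non-coding gene BALR6 at least 7.47-fold, each from background (largest adjusted p = 3.12e-05). The deepest falls were in DTX1, in ITGA1, an integrin chain for collagen (at least 50.1-fold, adjusted p = 1.8e-05), and in CD1E, a CD1 antigen of cortical thymocytes, from 13.12 to 8.11 (-5.01 ± 0.16, adjusted p = 2.04e-05). GAS2 (-4.85 ± 0.47) and the non-coding LINC01120 (-4.68 ± 0.25) followed, and GAS2 was at log2 4.42 and 2.76 on the persister arrays. MALAT1, a nuclear non-coding RNA, changed by -4.71 ± 0.78 (adjusted p = 0.0126), but its 11 other probe sets ranged from -4.99 to 1.30, and the call was lost without naive array 1 or naive array 2 (highest adjusted p = 0.104) and with either covariate (0.0512 and 0.052).

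In total 1501 genes passed the threshold in DND-41, 968 higher and 533 lower, and 658 of them changed at least 2-fold. The split depended on the probe sets used: 1302 were higher and 1194 lower with every probe set, and 684 and 629 with the mean of a gene's probe sets. Fitted without the KOPT-K1 arrays, DND-41 gave 107 genes, 56 higher and 51 lower. The count of 1501 also depended on each array of the fit, those of KOPT-K1 included, since the 4 groups share 1 estimate of the spread. It fell without any naive array or either KOPT-K1 persister array, and rose without either DND-41 persister array (range below). Of the 65 genes named in the text that passed here 24 lost their call without an array, 15 with the hybridization controls as a covariate and 14 with the 3'/5' ratio. With each line fitted alone, 44 values of named genes lost their call over both lines. With the hybridization controls the count was 625, of which 574 were shared, and with the 3'/5' ratio 798 of 1364 were shared.

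Among the fixed lists in DND-41, Notch target genes stood below other genes, with a median of -0.81 relative to all genes (-0.54 with genes at background set to their bound). That median was -0.48 with the 3'/5' ratio as a covariate and -0.01 without the filter. Of 16 measured members 8 fell and 1 rose, and 9 fell and 1 rose adjusted over the list alone (camera adjusted p = 8.78e-06; adjusted p = 0.165 with an estimated correlation). Ribosome biogenesis genes stood at -0.57: 5 of 21 fell and 7 adjusted over the list alone (adjusted p = 6.57e-06; 0.191 with an estimated correlation), among them UTP20 (-1.70 ± 0.41), WDR43 (-0.71 ± 0.14) and POLR1B (-0.65 ± 0.15). These 3 calls were lost without either naive array of either line (highest adjusted p = 0.197, 0.156 and 0.173), and that of UTP20 also without either KOPT-K1 persister array. In limma 0 of the 21 genes passed with the hybridization controls as a covariate, and 11 were lower at an unadjusted p under 0.05 (list adjusted p = 2.27e-06). The number lower was 0 without any naive array, 3 without either KOPT-K1 persister array, 8 without DND-41 persister array 1 and 10 without array 2. Immature thymocyte genes stood at -0.63, with 7 of 15 lower (4 without naive array 1) and 7 adjusted over the list alone (adjusted p = 2.39e-05; 0.303 with an estimated correlation), led by CD1E and CD1A (-2.53 ± 0.17).

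Mature and effector T-cell genes stood above other genes in DND-41, at 1.08. Of 10 measured members 6 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.0357; 0.303 with an estimated correlation; the fall was not past the threshold after median centring). GZMA led the list, with PRDM1, a regulator of terminal lymphocyte differentiation (2.72 ± 0.24), and KLF2, a quiescence and trafficking factor (at least 2.44-fold). KLF2 read the same log2 value, 5.286, on both DND-41 persister arrays, KOPT-K1 naive array 2 and KOPT-K1 persister array 1. The size of its rise is therefore in doubt. The list's call was lost without persister array 2 (0.337), without either KOPT-K1 naive array (0.061), with each line fitted alone (0.106) and without the filter (0.149), where the median was 0.05. Immediate early genes stood at 0.66, with 6 of 15 higher (3 without either naive array), 7 adjusted over the list alone, and MYC lower (adjusted p = 0.0197; 0.303 with an estimated correlation; 0.108 without persister array 2). FOSL2 (3.35 ± 0.32), JUND (2.06 ± 0.17; other probe set 0.44) and IER3 (1.78 ± 0.25) rose, that of IER3 not past the threshold without naive array 1 or naive array 2 (highest 0.0733). Lysosome and autophagy genes stood at 0.49, with 4 of 17 higher (0 without either naive array, 2 without either KOPT-K1 naive array and 11 without persister array 2) and 11 adjusted over the list alone (adjusted p = 0.00196; 0.558 with an estimated correlation; 0.0581 with the 3'/5' ratio as a covariate). WIPI1 (1.45 ± 0.25), GABARAPL1 (1.06 ± 0.28; other probe set 0.27) and TFEB (1.05 ± 0.27; other probe set 0.46), the last a master regulator of lysosomal genes, rose, and each lost its call without naive array 1 or naive array 2 (highest adjusted p = 0.101, 0.221 and 0.216). GABARAPL1 lost it also without either persister array or KOPT-K1 naive array, and TFEB without any KOPT-K1 array. With the hybridization controls as a covariate 1 of the 17 lysosome and autophagy genes was higher past the threshold.

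Other lists in DND-41 did not pass the list test with all arrays, though members did. T-cell receptor signalling genes split, with 5 of 22 higher and 6 lower (adjusted p = 0.239), but 2 higher and at most 3 lower without either naive array, and 3 lower without any KOPT-K1 array. THEMIS, a thymocyte selection factor, fell by 4.18 ± 0.12, while the phosphatase PTPRC (CD45) rose by 2.15 ± 0.23, with another probe set at -1.35. T-lineage transcription factors had 5 of 17 lower and 1 higher (adjusted p = 0.0561), and the list passed without naive array 2 (0.0288) and without persister array 2 (0.00252), with 3 lower without either naive array and 8 without persister array 2. It had falls in ID3 (-2.57 ± 0.29), IKZF2 (-2.04 ± 0.14) and LEF1 (-1.46 ± 0.12). Of PI3K, AKT and mTOR genes 5 of 26 rose (adjusted p = 0.127), led by PIK3R5 (2.65 ± 0.18), but 2 without either naive array and 9 without either persister array, and the list passed without persister array 1 (0.0292), with the 3'/5' ratio as a covariate (0.023) and without the filter (0.0214). Of cell cycle inhibitors and p53 targets 5 of 15 rose (adjusted p = 0.284), 2 without either naive array and 8 without persister array 1, among them the CDK inhibitor CDKN2D (2.58 ± 0.19) and TP53INP1 (2.52 ± 0.17). Oxidative phosphorylation and DNA replication stood at -0.12 (adjusted p = 0.481; 0.0292 without persister array 1 and 0.0263 with the 3'/5' ratio) and -0.13 (adjusted p = 0.56), and glycolysis had a median of -0.05 and a mean of 0.06 (adjusted p = 0.981).

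The strongest rises in KOPT-K1 persister cells were in genes low or at background in naive KOPT-K1 cells. ZNF521, a zinc finger regulator of progenitor cells, rose at least 65.6-fold (adjusted p = 9.33e-07), with 7.38 at its other probe set. KRT1, a keratin, rose at least 58.9-fold (adjusted p = 9.33e-07) and the adhesion gene NEGR1 at least 111-fold (adjusted p = 6.75e-05; other probe sets 1.29 and 6.55). RAG1, which starts antigen receptor rearrangement, rose from log2 5.95 to 13.28 (7.33 ± 0.26, adjusted p = 1.12e-05), against 14.37 in naive DND-41 cells. ZNF595 rose by 7.00 ± 0.27. The probe set used for RARA, a retinoic acid receptor gene, rose at least 124-fold (adjusted p = 0.00101), but its other probe set changed by -0.24, and with the hybridization controls as a covariate its change was 2.18 (adjusted p = 0.26). The falls were led by CD1E, from 13.71 to 6.81 (-6.90 ± 0.16, adjusted p = 3.28e-06), SERHL2 (at least 48.2-fold), MYO7B (-6.64 ± 0.25), SH3TC1 (at least 27.3-fold), the inhibitory receptor CD300A (at least 47.9-fold) and RCBTB2 (-6.08 ± 0.13).

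In KOPT-K1 5062 genes passed the threshold, 1636 higher and 3426 lower, and 2444 changed at least 2-fold. The median of all genes was -0.20, and the split depended on the scaling: with every array centred on its median 2318 were higher and 2389 lower (50.8% lower, against 67.7%), and after quantile normalization 2011 and 2668 (57.0% lower). List values below are relative to that median. The count was 3230 without naive array 1 and 3070 without naive array 2. With the hybridization controls as a covariate 1645 genes passed, 1514 of them shared, but these controls differ between the KOPT-K1 groups themselves, so the covariate takes up part of the difference between groups. Of the 94 genes named in the text that passed here 28 lost their call with that covariate, and 7 without an array.

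Genes of growth and metabolism fell together in KOPT-K1. Ribosome biogenesis genes stood at -1.48, and 20 of 21 fell, also adjusted over the list alone (adjusted p = 2.45e-06; 0.171 with an estimated correlation), with NOP16 (-2.92 ± 0.21), BYSL (-2.53 ± 0.30) and MYBBP1A (-2.15 ± 0.15). Of 27 DNA replication genes 19 fell and none rose, 21 adjusted over the list alone (median -0.59, adjusted p = 0.000763; 0.171 with an estimated correlation), with GINS2 (-1.45 ± 0.18; other probe sets -0.02 and -1.83), the cyclin CCNE1 (-1.16 ± 0.13) and CDC6 (-1.12 ± 0.13). Of 21 oxidative phosphorylation genes 18 fell (11 without naive array 2), also adjusted over the list alone, and 13 after median centring (median -0.52, adjusted p = 0.000763; 0.488 with an estimated correlation), with UQCRC1 (-1.55 ± 0.29), NDUFA9 (-1.25 ± 0.18) and NDUFV1 (-1.11 ± 0.19). Glycolysis had 15 of 19 lower and 2 higher, also adjusted over the list alone (median -0.60, adjusted p = 0.00837; 0.488 with an estimated correlation), with PKM (-2.50 ± 0.23; other probe set -0.06), PFKM (-2.28 ± 0.12) and GPI (-1.76 ± 0.18). Cholesterol synthesis had 11 of 15 lower, 12 adjusted over the list alone (median -0.79, adjusted p = 0.00814; 0.201 with an estimated correlation and 0.222 with the hybridization controls), with DHCR7 (-1.96 ± 0.26), NSDHL (-1.51 ± 0.21) and LSS (-1.37 ± 0.17; other probe set -0.19). BYSL, CDC6 and NDUFV1 were not past the threshold with the hybridization controls as a covariate (adjusted p = 0.0604, 0.0831 and 0.0707). With that covariate 10 ribosome biogenesis, 3 DNA replication, 3 oxidative phosphorylation, 6 glycolysis and 4 cholesterol synthesis genes fell past the threshold.

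T-lineage regulators rose in KOPT-K1. Of 17 T-lineage transcription factors 12 rose (7 without naive array 2) and 1 fell, 13 and 1 adjusted over the list alone (median 1.17, adjusted p = 1.33e-05; 0.342 with an estimated correlation). GATA3, which directs T-cell commitment, rose by 1.79 ± 0.23 and ID2 by 1.67 ± 0.23 (other probe set 0.72), while RUNX3 fell by 2.01 ± 0.24; ID2 and RUNX3 lost their calls with the hybridization controls as a covariate (0.103 and 0.0951). Of cell cycle inhibitors and p53 targets 8 of 15 rose and 1 fell, also adjusted over the list alone (median 0.85, adjusted p = 0.00248; 0.186 with an estimated correlation), with TP53INP1 (3.52 ± 0.17), ZMAT3 (2.24 ± 0.17) and CDKN2D (2.08 ± 0.20; 0.0556 with the hybridization controls). Of 10 cytokine and chemokine receptors 3 rose (5 without either DND-41 persister array), also adjusted over the list alone, and 6 after median centring (median 0.53, adjusted p = 0.015; 0.228 with an estimated correlation and 0.0776 with the hybridization controls). These were IL6ST (2.82-fold), CXCR4 (0.91 ± 0.11) and IFNAR1 (0.67 ± 0.13; other probe sets 0.15, 0.77 and -1.53), the last 2 lost with the hybridization controls (0.0712 and 0.149). T-cell receptor signalling had 8 of 22 higher and 3 lower, also adjusted over the list alone, or 9 and 0 after median centring, 5 and 4 higher without naive array 1 and 2, 5 without persister array 2, and none lower without any KOPT-K1 array or either DND-41 naive array (median 0.39, adjusted p = 0.0258; 0.242 with an estimated correlation and 0.393 with the hybridization controls). RASGRP1 (2.41 ± 0.18) and PTPRC (1.77 ± 0.23) rose, and CD2 (1.14 ± 0.32, adjusted p = 0.0239) lost its call without any KOPT-K1 array (highest adjusted p = 0.113) and turned to -0.14 with the hybridization controls (adjusted p = 0.899). With that covariate 3 T-lineage transcription factors, 4 cell cycle inhibitors and p53 targets, 1 cytokine receptor and 2 T-cell receptor signalling genes rose past the threshold, and none fell in these lists.

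Notch target genes had 10 of 16 lower and 3 higher in KOPT-K1, 11 and 3 adjusted over the list alone, with a median of -0.87 (-0.55 at the bound) that did not pass the list test (adjusted p = 0.121; 0.342 with an estimated correlation). CR2 (at least 9.49-fold) and IGF1R (-2.28 ± 0.17) fell beside DTX1 and MYC. With the hybridization controls as a covariate 6 Notch target genes were lower and 2 higher past the threshold. Other lists had members that moved without passing the list test. CD1B (-5.29 ± 0.29) fell with CD1E among 15 immature thymocyte genes while RAG1 rose, 6 higher and 5 lower in all. The histone demethylase KDM6B rose by 2.22 ± 0.15 among 29 BET and chromatin genes, 6 higher and 7 lower, or 8 and 3 after median centring; 10 were higher without either DND-41 persister array, and 2, 3 and 4 lower without naive array 1, naive array 2 and persister array 2. Mitosis genes had 14 of 24 lower and 1 higher, with PLK1 at -1.89 ± 0.39, but 5 and 3 after median centring, and 4 to 6 were lower without a KOPT-K1 array and 8 without either DND-41 naive array. With the hybridization controls as a covariate 4 mitosis genes were lower and 0 higher, and 0 BET and chromatin genes were lower and 2 higher. NKG7, a cytotoxic granule gene, fell by 1.94 ± 0.26, DDIT4, an inhibitor of mTOR, by 2.43 ± 0.13 and BCL2A1 at least 2.75-fold (adjusted p = 0.066 for BCL2A1 with the hybridization controls). The cystine transporter SLC7A11 fell at least 7.58-fold (other probe set -0.86) and TAP2 by 1.81 ± 0.16, within an MHC class I list of median 0.21 and mean -0.03 (adjusted p = 0.771). Of the interferon response genes OAS1 fell at least 4.23-fold (other probe set -1.91) and MX2 rose at least 5.1-fold. DUSP1 rose by 1.96 ± 0.12, the transporter ABCC5 by 2.81 ± 0.14 (other probe sets 0.48 and 3.03) and the integrin chain ITGA6 by 2.93 ± 0.11, while BAG3 (-1.93 ± 0.16; 0.0598 with the hybridization controls) and GLA (-1.32 ± 0.16; 0.0584) fell.

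**Figure D3:**
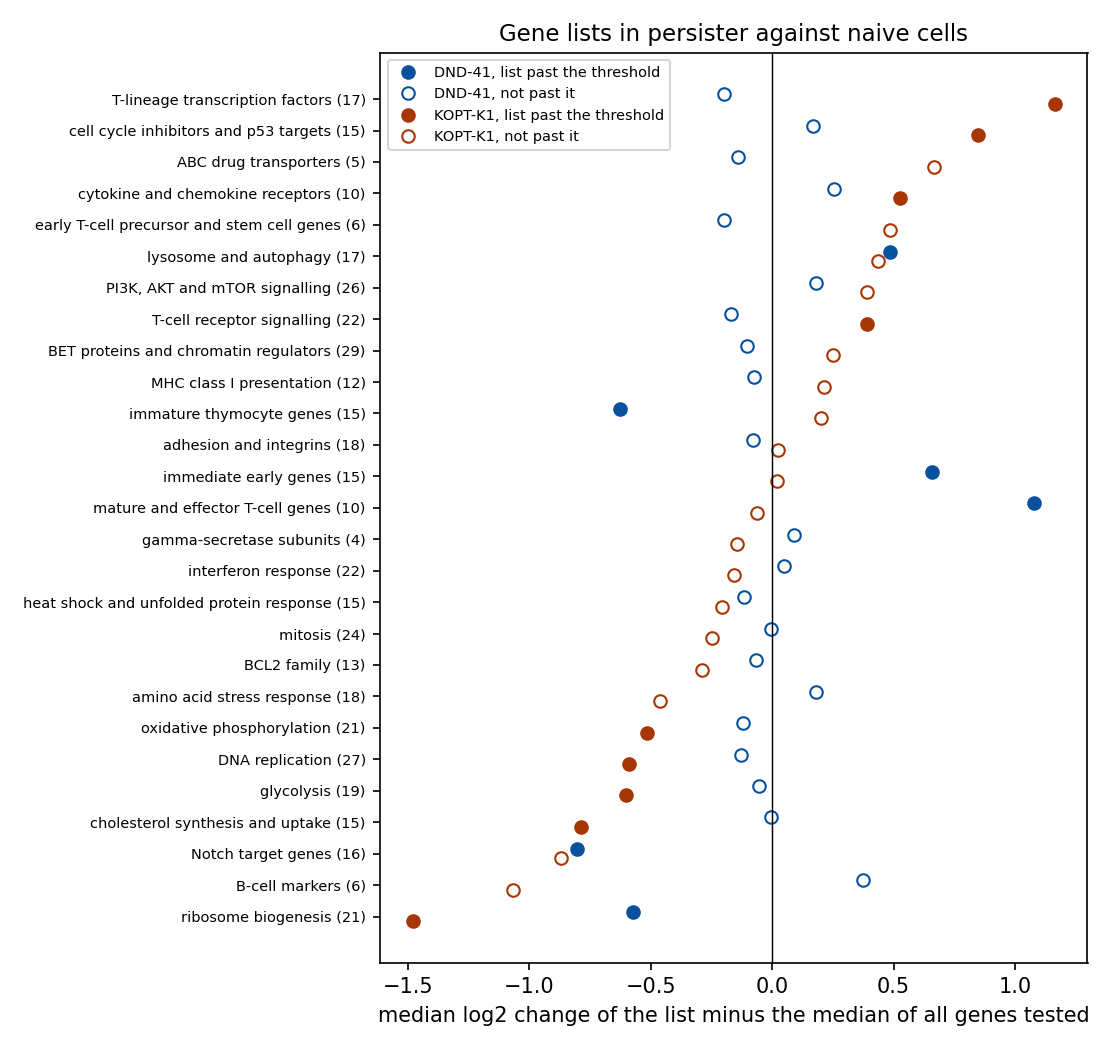
Each point is the median log2 change (persister minus naive) of the measured members of a fixed gene list, minus the median of all 10174 genes, in DND-41 (blue) or KOPT-K1 (red); filled points passed camera at a preset correlation of 0.01, and the number of members is in brackets. Ribosome biogenesis stands lowest in KOPT-K1, at -1.48, and T-lineage transcription factors highest, at 1.17; the list of stromal and epithelial markers is not drawn.

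Whether the lines changed differently was tested directly. The changes of 3810 genes differed between the lines, 904 higher and 2906 lower in KOPT-K1 relative to DND-41, or 1191 and 1792 after median centring. RASEF, a RAB family GTPase, rose 48.6-fold in KOPT-K1 and fell by 1.53 ± 0.33 in DND-41, a difference of 7.13 (adjusted p = 0.000169). Its fall in DND-41 was lost without DND-41 naive 1, DND-41 persister 1 or any KOPT-K1 array (highest adjusted p = 0.142). The angiogenic factor VEGFA fell at least 18.7-fold in KOPT-K1 and rose by 1.15 ± 0.11 in DND-41 (adjusted p of the difference 9.51e-06), although its other probe set changed by -0.79 and 0.08. PRR5, a component of mTOR complex 2, fell at least 6.33-fold in KOPT-K1 and changed by 2.06 ± 0.48 in DND-41 (adjusted p of the difference 0.00123; other probe set -2.65 and 0.05). As lists, T-lineage transcription factors (1.38, adjusted p = 3.93e-07), immature thymocyte genes (1.05, 0.00627) and T-cell receptor signalling (0.63, 0.00501) stood higher in KOPT-K1, and ribosome biogenesis (-0.88, 0.00225), glycolysis (-0.71, 0.00368) and cholesterol synthesis (-0.65, 0.00627) lower. With an estimated correlation their adjusted p-values were 0.328, 0.339, 0.262, 0.262, 0.379 and 0.262. They were 1.82e-06, 0.0767, 0.0763, 0.0152, 0.0056 and 0.0767 with the hybridization controls as a covariate. Notch target genes passed the list test in DND-41 alone, but the difference between the lines did not pass it (median -0.13, mean 0.28, adjusted p = 0.472). Without single arrays the gene count ran from 1762 (DND-41 naive 1) to 6450 (DND-41 persister 2), with 2170 without DND-41 naive 2, 1914 and 1819 without KOPT-K1 naive 1 and 2, and 2392 and 2474 without KOPT-K1 persister 1 and 2.

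The lines shared more changes than independent lists would. Of 812 genes past the threshold in both, 607 changed the same way and 205 the opposite way. Of these, 345 were higher in both (156 for independent lists; odds ratio 3.39, Fisher's exact p = 5.25e-56) and 262 lower in both (179; odds ratio 1.98, p = 4.3e-14), and genes are not independent replicates. The 2 comparisons also share 1 estimate of spread per gene, which favours calls in both lines, so the lists are not independent. With the mean of a gene's probe sets 197 genes were higher in both and 284 lower, with every probe set 397 and 421, and after median centring 475 and 209. With each line fitted alone 54 were shared, 24 higher and 30 lower, and the shared count also fell with the hybridization controls as a covariate (below). TP53INP1, PTPRC and CDKN2D were among those higher in both, and DTX1, CD1E, CD1A and IGLL1 among those lower in both. Across all genes the changes correlated with Pearson's r = 0.155 and Spearman's rho = 0.224, again across genes that are not replicates. The shared count was 127 and 128 without DND-41 naive 1 and 2, 1477 and 1410 without DND-41 persister 1 and 2, 249 and 229 without KOPT-K1 naive 1 and 2, and 352 and 368 without KOPT-K1 persister 1 and 2.

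**Figure D4:**
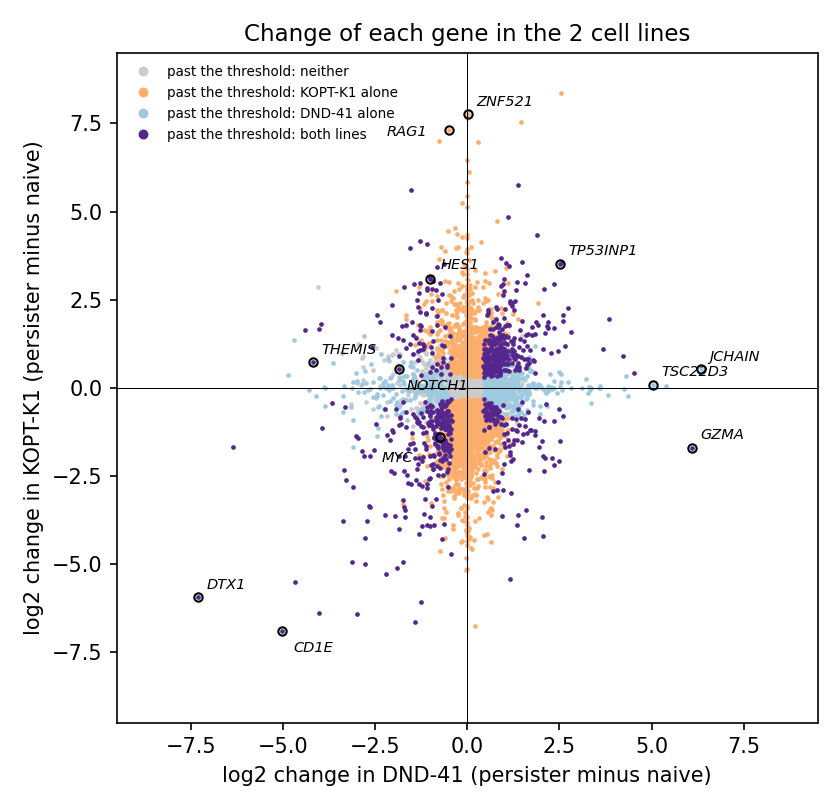
Each of 10174 genes is plotted by its log2 change in DND-41 (horizontal axis) and in KOPT-K1 (vertical axis), coloured by whether it passed the threshold in both, either or neither line. DTX1 and CD1E lie far down in both lines, JCHAIN, TSC22D3 and GZMA far right, and RAG1 and ZNF521 far up.

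On average over both lines 4509 genes passed the threshold, 1991 higher and 2518 lower (2603 and 1818 after median centring), and 1014 changed at least 2-fold. Ribosome biogenesis (-1.03, all 21 members lower, 21 also adjusted over the list alone and 18 after median centring; adjusted p = 5.12e-08) and Notch target genes (-1.03, 12 of 16 lower and 3 higher, also adjusted over the list alone; adjusted p = 0.00346) stood below other genes. Both had adjusted p = 0.149 with an estimated correlation. Only 786 genes passed with the hybridization controls as a covariate, among them 6 ribosome biogenesis genes and 6 Notch target genes that fell and 1 Notch target gene that rose (list adjusted p = 5.92e-06 and 0.011). The gene count was 2985 without DND-41 naive 2 and 2892 without KOPT-K1 naive 2.

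The naive lines differed as a background to these changes. Between them 4158 genes passed the threshold, 1807 higher in KOPT-K1 and 2351 higher in DND-41. ITM2A (at least 975-fold), the peroxidase PRDX2 (766), FKBP5 (523), a glucocorticoid-responsive gene, the serine synthesis enzyme PSAT1 (371) and CTHRC1 (325) were at background in DND-41 and high in KOPT-K1. NLGN4X (at least 625-fold), TENT5C (377), SMPD3 (334), MME, known as CD10 (246), and LRIF1 (234) were at background in KOPT-K1 and high in DND-41. The largest adjusted p of these 10 genes was 4e-07. These folds hold for the probe sets used, and FKBP5 has others that changed differently in DND-41 (below). The count was 2585 and 2688 without DND-41 naive 1 and 2, and 2729 and 2519 without KOPT-K1 naive 1 and 2. Between the persister lines 6621 genes differed.

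Markers of other cell types were examined in the same arrays. No myeloid or NK-cell marker passed the filter. Of the erythroid markers TFRC, a transferrin receptor of dividing cells, was measured. It fell past the threshold in KOPT-K1, from log2 14.48 to 13.91, but not with the hybridization controls as a covariate. Of the stromal markers COL1A1 and VIM were measured. VIM fell by 0.87 ± 0.17 in KOPT-K1 (other probe set -0.38), not past the threshold with the hybridization controls (-0.26, adjusted p = 0.65). Of 6 measured B-cell markers 2 rose and 1 fell past the threshold in DND-41, and 1 rose and 4 fell in KOPT-K1. IGLL1, a surrogate light chain gene, fell by 2.67 ± 0.22 in DND-41 and by 3.35 ± 0.22 in KOPT-K1. EBF1 went from log2 9.41 to 10.48 in DND-41 and from 2.24 to 4.02 in KOPT-K1. CD79A went from 9.94 to 10.94 in DND-41 and from 7.42 to 6.39 in KOPT-K1. CD79B rose by 2.02 ± 0.34 in DND-41, lost without naive array 1 or naive array 2 (highest adjusted p = 0.11) and with the hybridization controls (0.066) or the 3'/5' ratio (0.0607), and fell by 1.51 ± 0.34 in KOPT-K1, lost without naive array 2 or persister array 1 (highest 0.0732). VPREB1 was at least 1.18-fold lower in KOPT-K1 persister cells. As a list the B-cell markers did not pass in DND-41 (median 0.38, mean -0.02, adjusted p = 0.981) or KOPT-K1 (-1.07, adjusted p = 0.294).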

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

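The tests of the DND-41 persister arrays, of exchanged labels and of the HES1 probe sets were chosen after their results were seen, and the hybridization controls entered the weighing after the data were seen.

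DND-41 persister array 1 stood apart, with a 3' against 5' signal of 3.17 where the other 7 arrays ran from 0.993 to 1.71, and the SD between the 2 persister arrays was 0.414. If its weak 5' signal had produced the DND-41 changes, most would be lost without it, and 91.9% of the 1501 genes were past the threshold in the same direction without that array, but 98.8% were so without array 2, so calling genes on 2 agreeing arrays fixes this outcome. Array 2 also had a GAPDH 3' minus 5' signal of 0.563, against at most 0.198 on the 6 arrays of other groups, so weak 5' signal and a response of the cells cannot be told apart for these 1501 genes, of which 798 were still called with the 3'/5' ratio as a covariate. Whether 5' signal sets the differences between the 2 persister arrays stays open, because those differences correlated at -0.445, 0.279 and 0.0535 with the same contrast in the other replicate pairs. No biological explanation for a difference between replicates was tested.

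In KOPT-K1 more genes fell than rose, 67.7% of those past the threshold against 50.8% after median centring. If the scaling of the arrays alone had lowered the values, hybridization controls added in a fixed amount should have fallen with the genes, but they rose by 1.68 ± 0.33. A rise was set down beforehand as speaking against the scaling, yet that bound was wrong: the rise dwarfs the shift of -0.20 in the median gene, so the controls are no fixed reference for the genes, whatever moved them, which was not tested. Scaling and a broad fall of RNA therefore cannot be told apart for these genes, since the controls differ with the groups. The excess of falls did not extend to probe sets without a single gene symbol, of which 984 were higher and 751 lower. Less RNA per persister cell stays open as a biological explanation, untested, and values normalized over arrays cannot test it. List values relative to the median of all genes are not moved by a shift common to all genes of an array.

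HES1 and NOTCH1 changed in opposite directions in the 2 lines although DTX1 fell in both. Exchanged labels in KOPT-K1 would make DTX1 higher in the arrays labelled persister, and it was lower by more than its error (-5.94 ± 0.22), which argues against an exchange. For HES1 in KOPT-K1 a second probe set changed by 2.63, which argues against a single faulty probe set, but in DND-41 the second gave 0.30 against -1.01, so a probe set that misses part of the transcripts may account for the fall there. NOTCH1 had 1 measured probe set, and its KOPT-K1 rise ended with the hybridization controls as a covariate (0.48 ± 0.32, against 0.53 ± 0.12 without) because the error grew. A route to HES1 that differs between the lines is a biological hypothesis that these arrays do not test.

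Below are results whose change differed between the lines, given as the KOPT-K1 change minus the DND-41 change in log2, each with an adjusted p under 0.05; where a group lies at background the value is a fitted one and no bound. In all 3810 genes differed. For DTX1, SH3TC1 and CD300A, among others, both persister groups lay under log2 4. Their falls are therefore lower bounds in both lines, and the differences between those falls are not resolved. Some differences turn or nearly vanish at another probe set of the gene, given here by its DND-41 and KOPT-K1 changes. They turn for IL7R (-3.27 and -1.76), JUND (0.44 and 0.67), POLR1B (-1.32 and 2.15) and NEGR1 (2.41 and 1.29). They nearly vanish for RARA (-0.30 and -0.24), SLC7A11 (-0.90 and -0.86) and GINS2 (-0.01 and -0.02). They are much smaller for, among others, FKBP5 (0.66 and 0.35), PKM (0.28 and -0.06) and ID2 (0.40 and 0.72). Notch pathway and fixed genes had values of NOTCH1 2.39, NOTCH3 2.60, HES1 4.08, HES4 -2.47, DTX1 1.36, IL7R -3.37, BCL2 -1.19, CR2 -2.66, IGF1R -1.67 and RUNX3 -2.59. Among the strongest DND-41 genes the values were JCHAIN -5.82, GZMA -7.79, NOG -5.33, TSC22D3 -4.95, IQGAP2 -4.09, BALR6 -4.58, ITGA1 4.67, CD1E -1.89, GAS2 5.21 and MALAT1 6.07, and among the strongest KOPT-K1 genes RARA 5.83, ZNF521 7.76, KRT1 7.64, NEGR1 6.08, RAG1 7.83, ZNF595 7.75, SERHL2 -6.98, MYO7B -5.23, SH3TC1 -3.43, CD300A -2.35 and RCBTB2 -4.81. T-cell genes gave THEMIS 4.91, CD2 2.81, RASGRP1 1.26, CD1A 0.77, CD1B -3.09, ID3 3.73, IKZF2 3.54, LEF1 2.42, GATA3 3.06, ID2 1.88, PRDM1 -2.56, KLF2 -2.46 and NKG7 -3.98. Ribosome biogenesis, replication and mitosis genes gave NOP16 -2.41, BYSL -2.98, MYBBP1A -2.13, WDR43 -0.75, POLR1B -1.35, GINS2 -1.22, CCNE1 -1.59, CDC6 -1.02 and PLK1 -2.06. Metabolic genes gave UQCRC1 -1.92, NDUFA9 -1.25, NDUFV1 -1.13, DHCR7 -2.07, NSDHL -1.84, LSS -1.49, PKM -2.24, PFKM -1.55, GPI -1.11, SLC7A11 -3.65 and PSAT1 -1.60. Signalling, cell cycle and survival genes gave PIK3R5 -1.46, DDIT4 -3.37, TP53INP1 0.99, ZMAT3 1.95, BCL2A1 -1.95, IL6ST 1.97, CXCR4 0.85, FOSL2 -3.79, JUND -0.95, IER3 -2.17, DUSP1 1.18, KDM6B 2.42, BAG3 -0.92, VEGFA -6.56, PRR5 -6.28, RASEF 7.13, PTCH1 5.85, TXNIP -1.25, BCL6 2.44, STAT4 -5.70, SH3BP5 6.03, P2RY10 -1.89, YBX3 -1.49, TIMP2 0.98, FKBP5 -3.38 and CTHRC1 -1.35. Lysosome, immune response, transporter, adhesion and marker genes gave WIPI1 -2.14, TFEB -1.80, GLA -1.67, OAS1 -3.59, MX2 3.14, TAP2 -1.34, ABCC5 3.03, ITGA6 2.92, CD79B -3.53, VPREB1 -2.01 and VIM -0.92. The median difference over all genes was -0.40, a shift that small negative values include, and VIM did not pass after median centring.

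Gene lists differed between the lines too, by the median difference relative to all genes: ribosome biogenesis -0.88, cholesterol synthesis -0.65, glycolysis -0.71, oxidative phosphorylation -0.33, DNA replication -0.35, amino acid stress response -0.57, cell cycle inhibitors and p53 targets 0.33, T-cell receptor signalling 0.63, immature thymocyte genes 1.05 and T-lineage transcription factors 1.38. Their largest adjusted p was 0.0485, and none passed with an estimated correlation, where the smallest adjusted p was 0.262. With the hybridization controls as a covariate cholesterol synthesis (0.0767), DNA replication (0.0705), T-cell receptor signalling (0.0763) and immature thymocyte genes (0.0767) did not pass. Amino acid stress response was lost without DND-41 naive 1 (0.0505), DND-41 persister 1 (0.0681) or 2 (0.0693), KOPT-K1 persister 1 (0.0533) or 2 (0.114), and with the 3'/5' ratio (0.0505), and cell cycle inhibitors and p53 targets without DND-41 naive 1 (0.0505), DND-41 persister 2 (0.0693) or KOPT-K1 persister 2 (0.0665). Probe sets without a single gene symbol, which no comparison above uses, also changed: of 3696 measured, 422 passed the threshold in DND-41 (159 higher and 263 lower) and 1735 in KOPT-K1 (984 and 751).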

How the results depend on the processing

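The 3'/5' and hybridization covariates and the crossed numbers were chosen after the data were seen. All other settings were planned, but holding the probe set per gene in the leave-one-out and quantile settings was decided after HES1 changed sign. The cause of a difference was not tested unless stated. Values at log2 4 or below, 62.4% of all, limit what can be said of weakly expressed genes. Of the values of named genes under the alternatives 5191 kept direction and side of the threshold, 81 gained it, 348 lost it and 6 reversed, and of those of gene lists 1124, 39, 24 and 1; 167 sign changes of values not past the threshold count as kept. Genes past the threshold (1501 in DND-41, 5062 in KOPT-K1, 3810 for the difference, 4509 on average, 4158 between naive lines, 607 shared) moved by over 1.5 times as follows and with the replicate block (below), and other counts stayed within that. Without the filter, with more genes tested, they were 862, 2413 (difference) and 392 (shared), and with every probe set 2496, 7790 and 6022 (difference). Fitted alone, with 2 residual degrees of freedom, DND-41 gave 107 and the shared count was 54, while KOPT-K1 alone, also with 2, gave 6355. The SD between replicates was 0.414 in DND-41 persister cells and at most 0.219 in the other groups. The joint fit shares 1 estimate of the spread over all groups. Its errors for DND-41 can therefore be too small, which bears on the 1501 and the 607. A 2-fold minimum gave 658, 2444, 1014 (average), 2234 (naive lines) and 154 (shared), and an adjusted p under 0.01 gave 403, 3210, 1598, 2574, 2689 and 148. With the hybridization controls 625, 1645, 786 (average) and 169 (shared) passed. Leaving out single arrays, where the lone array left is assumed to vary like the others, gave 290 to 4510, 3070 to 6609, 1762 to 6450, 2892 to 6235, 2519 to 5961 and 127 to 1477. Lists past the threshold (6 in DND-41, 9 in KOPT-K1) became 0 and 0 with an estimated correlation, 15 and 19 with fry, and 17 in KOPT-K1 with every probe set. The Notch list in DND-41 (-0.81) had adjusted p = 0.165 with an estimated correlation, within 3.43e-06 to 0.165 over all alternatives; in KOPT-K1 it passed with every probe set (-1.21, 0.0249) and fry (-0.87, 3.35e-05), within 3.35e-05 to 0.342. Reversed were heat shock genes in DND-41, a median of -0.11 that fry put upward (0.047), PRDX2 in KOPT-K1 as a mean of its probe sets (0.78), and in KOPT-K1 with the hybridization controls EZH1 (-0.033), PMAIP1 (0.41), CD2 (-0.14), ITGA2 (0.078) and ID3 (-0.093).

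The replicate numbers did not pair the arrays, so the replicate block, with 2 residual degrees of freedom, is no better estimate: it gave 404 genes in DND-41, 3918 in KOPT-K1, 2145 for the difference and 152 shared. Crossed numbers in DND-41 gave 1765 there and 5152 in KOPT-K1. Of 34 splits of the 8 arrays into 4 and 4 with the line as a covariate, 1, the real one, called as many genes (1160, against 63 in the next). All but 2, the real one and the one with 63, part replicates of a group, which puts the group difference into the spread, and 2 splits are too few for a share under 0.05.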

Other observations

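The gene list tests for FOXO and glucocorticoid targets were chosen after TSC22D3 had been seen, the hedgehog test before its result was known, and the genes in the next paragraph after their values were seen.

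Some genes outside the fixed lists moved strongly in both lines. TIMP2, an inhibitor of matrix metalloproteases, rose by 2.55 ± 0.18 in DND-41 (adjusted p = 0.000473) and by 3.53 ± 0.18 in KOPT-K1 (adjusted p = 3.13e-05), and BCL6, a transcriptional repressor of lymphocyte differentiation, by 1.90 ± 0.22 (0.00353) and 4.34 ± 0.22 (3.34e-05). The receptor P2RY10 rose by 3.83 ± 0.18 and 1.95 ± 0.18, and TXNIP, which restrains glucose uptake, by 2.82 ± 0.17 and 1.57 ± 0.17. YBX3, a cold shock domain protein, changed by -2.77 ± 0.11 and -4.26 ± 0.11. Others went opposite ways. STAT4, a cytokine signalling factor, rose by 2.02 ± 0.11 in DND-41 and fell by 3.68 ± 0.11 in KOPT-K1, a fitted value since it ended just under log2 4, and SH3BP5 fell by 4.40 ± 0.14 in DND-41 and rose by 1.63 ± 0.14 in KOPT-K1. These genes kept their calls without each array in turn, and with the hybridization controls as a covariate all but SH3BP5 in KOPT-K1 (1.14, adjusted p = 0.0592).

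TSC22D3 is a known target of FOXO factors and of the glucocorticoid receptor, and its rise in DND-41 raised the hypothesis that either programme was more active there. FOXO targets without TSC22D3 stood above other genes in DND-41 by 0.475, with 7 of 18 higher and 1 lower (camera p = 0.00734, Benjamini-Hochberg 0.022; p = 0.163 with an estimated correlation). Glucocorticoid response genes stood above by 0.572, with 8 of 14 higher and 1 lower (p = 0.0161, Benjamini-Hochberg 0.0241; p = 0.124 with an estimated correlation). Both programmes may therefore have risen, but the lists stood higher in KOPT-K1 as well (0.911 and 1.01), where TSC22D3 stayed at background, and several members lie in fixed lists whose results had been seen. FKBP5, another glucocorticoid-responsive gene, rose at least 3.25-fold in DND-41 at the probe set used, while its other probe sets changed by 0.44 and 0.66.

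PTCH1, a receptor and target of hedgehog signalling, rose from background to log2 9.24 in KOPT-K1 (5.85 ± 0.12, a fitted value; adjusted p = 2.19e-06). The hypothesis that hedgehog genes rose with it stays open: the 8 other measured genes had a relative median of 0.177, with 1 higher and 0 lower at the threshold over all genes (limma camera over genes, adjusted p = 0.353). The 1 higher was HHIP (1.36 ± 0.14, limma adjusted p = 0.000418).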
